A study of Mus musculus with 48 samples.

How the data were processed

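RNA was sequenced from 48 whole subcutaneous tumours, each from a different female BALB/c mouse aged 8 to 9 weeks. AB1, a mouse mesothelioma line, gave 24 tumours removed on day 8, and Renca, a mouse kidney cancer line, gave 24 tumours removed on day 10. Per the labels, removal came before treatment with antibodies against CTLA4 and PD-L1, and each mouse was later classed as a responder or a non-responder. This gave 4 groups of 12 mice. Per the labels' protocols, frozen tumours were homogenised in Trizol and the RNA was cleaned on columns before Illumina libraries were made.

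The deposited table holds raw counts per gene, whole numbers that were not normalised, for 39637 mouse Ensembl genes in 48 libraries. Of these identifiers, 39461 matched GENCODE M21 (GRCm38), from which the coordinates given here were taken, and 8466 genes had no count in any library. The submitters' processing notes name bcl2fastq 2.18.0.12, HISAT2 2.0.4 and StringTie 1.3.0. They also name the human builds GRCh37 and hg19, although the identifiers in the table are mouse. The counting tool, the annotation, the mouse build and the strand setting are not given in the sources used here, so coordinates from GRCm38 are not known to be those of the authors' build. Reads of near-identical genes could have been divided between copies by the authors' counting, and values of the pseudogenes Tpt1-ps5, Tpt1-ps6 and Krt8-ps, of Amd2, and of the families holding Mrgpra2a and Mrgpra2b, Klrc1 and Klrc2, H2-D1 and H2-Q7, Gbp6 and Gbp8, and Gzmd are uncertain for that reason. The table analysed does not hold every mouse gene. Ifng, Gzma, Gzmb, Prf1, Cd74, Ciita, Stat2, Isg15, Adgre1 and the mitochondrially encoded genes are not analysed here, and library totals are sums over the genes in the table.

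Library totals ran from 16.4 to 27.8 M counts (M for mega). Groups were compared with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the filterByExpr filter, the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. Each tumour was fitted separately with the sequencing flow cell as a term. A shared response effect and the difference of the response effect between tumours were fitted over all 48 libraries with 4 flow cell levels. AB1 and Renca were compared with response as a term, because flow cell, day of removal and tumour cannot be separated. The standard error of a log2 fold change is its size divided by the square root of F. Every log2 fold change of response is responder against non-responder.

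Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, beside an estimated correlation, fry and a two-sided permutation test of the list score. A list score is the mean log2 CPM of its tested members in a library, and 100000 resamples were drawn, so that 1e-05 is the smallest p they can give. Lists were fixed for 35 themes before the data were examined. They covered the type I and type II interferon responses, MHC class I and class II presentation, T cells, cytotoxic lymphocytes, NK cells, regulatory T cells, checkpoint molecules, B and plasma cells, dendritic cells of 3 kinds, macrophages, monocytes, neutrophils, mast cells and eosinophils. They also covered fibroblasts and matrix, the TGF-beta response, blood and lymphatic endothelium, proliferation, hypoxia and glycolysis, oxidative phosphorylation, chemokines, inflammatory cytokines and immediate early genes. The remaining lists marked other tissues, namely skin, skeletal muscle, fat, mammary epithelium, blood, mesothelium and renal tubule, and mitochondrially encoded genes, which had 0 members in the table, leaving 34 tested lists. Pan-leukocyte, osteoclast and bone lists were written later. With redrawn response labels of the same libraries, camera at the preset correlation passed a median of 13 of the 34 lists in AB1 and 11 in Renca. Passing camera alone is therefore weak evidence of a response effect. The designs, the lists, the rule for named genes and most alternatives were fixed before the data were examined. That rule took, in each responder comparison, the 10 largest rises and the 10 largest falls among passing genes with a mean log2 CPM of at least 1, leaving out symbols made of Gm and digits, Rik symbols and antibody and T cell receptor segments. It took 6 and 6 between tumours, the 5 and 5 smallest p for the difference of effects, the 3 members of smallest p in each passing list, and a fixed panel of checkpoint, interferon and lymphocyte genes. Some genes that the rule took are not reported here, while counts and list tests include them.

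AB1 replicates 1 to 5 and Renca replicates 1 to 6 were run on the first flow cell of their tumour and the others on the second, with response balanced in each. Same-numbered responders and non-responders shared a lane in 12 of 12 pairs of each tumour, per the labels, so the numbers mark a shared batch. Deviations from the group means of same-numbered libraries correlated from -0.0914 to 0.513 in AB1 and from -0.125 to 0.263 in Renca. Responders and non-responders carried different index sequences throughout, so an index effect cannot be separated from response. No pair of libraries within a group was a duplicate, since the smallest chi-square per degree of freedom was 7.49, and pairs from different groups were not compared. RNA purity ratios for carried-over salts and solvents averaged 2.18 in AB1 responders and 1.98 in AB1 non-responders (permutation p = 0.0371, adjusted 0.124). In Renca they averaged 1.99 and 2.12 (permutation p = 0.0185, adjusted 0.0925), the opposite direction. The adjustment also covered library totals and other technical measures, so balance of purity over response is not shown.

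Each test was checked on simulated counts with 50 genes changed at each of 4 sizes. At a log2 change of 0.5 it recovered 41 of 50 genes in the AB1 comparison (15859 genes), 46 in Renca (15778 genes), 45 for the shared effect (16800 genes), 33 for the difference between tumours (16920 genes) and 47 between tumours (16258 genes). At 0.25 it recovered 17, 37, 32, 14 and 32. Of the unchanged genes it called 6 of 15522, 10 of 15464, 11 of 16486, 2 of 16617 and 5 of 15896. Simulated genes were drawn independently and few were changed, unlike the data, so these rates need not hold for the real fits. Alternatives were size factors by median ratios, DESeq2 1.42.0, limma voom with quality weights, other filters, no flow cell term, a replicate block, RNA purity ratios as covariates, each flow cell alone, 1 fit of all libraries and leaving out each library. Skeletal muscle and pan-leukocyte scores as covariates and the omission of AB1 non-responders 3 and 7, alone or with responder 3, were added after seeing the data.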

Results

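Transcript counts were measured in whole tumours taken before checkpoint antibody treatment, to ask which genes differed between mice that later responded and mice that did not. AB1 is a mesothelioma model and Renca a kidney cancer model, both grown under the skin of BALB/c mice. Each tumour had 12 responders and 12 non-responders, and every library came from a separate mouse. Totals averaged 23.6 ± 0.431 M counts in AB1 responders, 24.2 ± 1.85 in AB1 non-responders, 20.7 ± 2.07 in Renca responders and 20.8 ± 2.23 in Renca non-responders (SD, n = 12 each). Totals did not pass a difference test in either tumour (adjusted permutation p = 0.628 in AB1 and 0.95 in Renca). The 10 most abundant genes took 4.71% of the counts in AB1 responders and 6.6% in AB1 non-responders (adjusted permutation p = 1e-04, from an unadjusted 1e-05 that is the smallest the test can give), and 6.47% and 6.24% in Renca (adjusted permutation p = 0.628).

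AB1 tumours of responders held more RNA of T cell, NK cell, interferon response, antigen presentation and neutrophil genes, and less of collagen and fibroblast genes, than AB1 tumours of non-responders, by camera on the lists of these genes. With an estimated correlation those lists did not pass, with adjusted p = 0.388 for type I interferon and 0.328 for the others. Cd8a, the alpha chain of the CD8 co-receptor (ENSMUSG00000053977, chromosome 6, 71373427 to 71379173), rose by 2.63 ± 0.30 on the log2 scale, from 6.58 ± 2.36 to 40.6 ± 20.2 CPM (SD, n = 12). Pdcd1, which encodes the receptor PD-1 (chromosome 1, 94038305 to 94052553), rose by 2.16 ± 0.24, and both genes exceeded the non-responder median in 12 of 12 responders. Col3a1, a fibrillar collagen, fell by 0.93 ± 0.14 and exceeded that median in 1 of 12. In the edgeR quasi-likelihood test, 9577 of 15859 genes passed, 4396 higher and 5181 lower in responders, and 1632 of them changed by at least 1 on the log2 scale, 1198 higher and 434 lower. Within flow cells the counts were 5816 in the first (3021 higher, 2795 lower) and 7725 in the second (4106 higher, 3619 lower), and with RNA purity ratios as covariates 4516 were higher and 4303 lower, so the balance turned. With a pan-leukocyte score as a covariate, edgeR called 0 genes (343 at an unadjusted p under 0.05, no other tool run), and that score correlated at 0.889 with response.

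The largest AB1 rise was that of Lcn2, an iron-siderophore binding protein of neutrophils and inflamed epithelium (chromosome 2, 32384633 to 32388252), at 3.89 ± 0.50 (adjusted p = 1.18e-06, 11 of 12 responders above the non-responder median). Gzmd, a granzyme, rose by 3.40 ± 0.48 and Pdcd1lg2, which encodes the PD-1 ligand PD-L2, by 3.32 ± 0.43. Pdcd1lg2 went from 6.80 ± 5.88 to 67.0 ± 33.4 CPM (SD, n = 12). Acod1, the itaconate-producing enzyme of activated macrophages, rose by 3.04 ± 0.48. Dnase1l3, a secreted DNase, rose by 3.11 ± 0.41, Inpp5j, an inositol phosphatase, by 3.01 ± 0.42 and Tlr12, a Toll-like receptor, by 2.87 ± 0.37. RP24-499N24.4 rose by 2.91 ± 0.38. The pseudogene Tpt1-ps5 rose by 3.51 ± 1.24 (adjusted p = 0.0182) but exceeded the non-responder median in 4 of 12 responders, and its value was -0.65 in the first flow cell alone. With the replicate number as a block it stood at 0.73 (adjusted p = 0.511).

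Among the largest AB1 falls, Dmp1, a bone and dentin matrix protein (chromosome 5, 104202613 to 104214102), fell by 3.30 ± 0.41 (adjusted p = 9.18e-07), and Col10a1, the collagen of hypertrophic cartilage (chromosome 10, 34389981 to 34397085), fell by 2.75 ± 0.43, from 466 ± 242 to 68.1 ± 57.7 CPM (SD, n = 12). For both, 0 of 12 responders exceeded the non-responder median. Krt5, a basal keratin of skin (chromosome 15, 101707070 to 101712898), fell by 4.68 ± 1.47 (adjusted p = 0.00853). The desmosomal Dsp fell by 3.22 ± 1.1 and Perp by 2.89 ± 1.08, Cdsn by 3.46 ± 1.08, Psors1c2 by 2.88 ± 1.17, Trim29 by 3.51 ± 1.11, and S100a3, a protein of the hair cuticle, by 2.78 ± 1.02. Krt5 stood at 223 CPM in non-responder 3 and 91.2 in non-responder 7, and at no more than 2.88 in the other non-responders, while responder 3 had 21.6. Without non-responders 3 and 7 the changes of Krt5, Trim29, Cdsn, Dsp, Perp and Psors1c2 were 0.32, 0.44, 0.27, 0.60, 1.17 and 0.35, and with responder 3 left out as well they were -2.04, -1.10, -1.22, -0.66, 0.17 and -1.08. Of these Krt5 (adjusted p = 0.0435), Trim29 (0.0313) and Cdsn (0.00259) passed, and Dsp (0.211), Perp (0.777) and Psors1c2 (0.0565) did not. Without non-responder 3 alone, Krt5 stood at -3.41 (adjusted p = 0.167), Trim29 at -1.48 (0.294), Cdsn at -1.03 (0.365), Dsp at -1.50 (0.331) and Perp at -0.96 (0.505). Without non-responder 7 alone, Dsp stood at -2.0 (adjusted p = 0.112) and Perp at -1.62 (0.216). Without non-responder 3, S100a3 stood at -0.11 (adjusted p = 0.906) and Psors1c2 at 0.32, and the call of Psors1c2 was lost in 8 of 24 fits that left out 1 library. Amd2 fell by 2.84 ± 1.04 and stood at -0.23 without non-responder 10 (adjusted p = 0.521). With the replicate number as a block, Dsp stood at -1.37 (adjusted p = 0.0726), Perp at -0.47 (0.627) and Amd2 at -0.70 (0.398).

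T cell, cytotoxic, NK cell, regulatory T cell and checkpoint lists rose in AB1 responders by camera, with adjusted p = 0.328 with an estimated correlation for each. All 21 tested members of the T cell list rose, with a median of 1.83, among them Cd247 at 1.95 ± 0.24, the zeta chain of the T cell receptor complex, and Sh2d1a at 2.27 ± 0.28. In the cytotoxic list 10 of 10 rose (median 2.23), including Cst7 at 2.15 ± 0.20 and Eomes, a transcription factor of cytotoxic cells, at 2.21 ± 0.25. In the NK cell list 17 of 17 rose (median 2.07), including Klrc1 at 2.52 ± 0.30, Txk at 1.98 ± 0.24, Il18rap at 0.94 ± 0.11 and the NK receptor gene Ncr1 at 2.07 ± 0.28. In the regulatory T cell list 11 of 12 rose (median 1.3), including Gpr83 at 2.15 ± 0.32, Izumo1r at 1.82 ± 0.29, Tnfrsf18 at 1.22 ± 0.20 and Foxp3 at 1.31 ± 0.28. Among checkpoint molecules 13 rose and 1 fell of 15 (median 1.32), including Cd86 at 1.5 ± 0.17, Vsir at 0.71 ± 0.08, Cd274, which encodes PD-L1, at 2.13 ± 0.37 and Ctla4 at 1.59 ± 0.31. Counts adjusted over the list alone were 21, 10, 17 and 11 higher, and 13 higher with 1 lower. Camera adjusted p were 1.05e-09, 6.7e-07, 5.18e-09, 0.000146 and 2.25e-05. Score permutation gave adjusted p = 4.86e-05 for each, from an unadjusted 1e-05 that is the smallest it can give.

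Interferon and antigen presentation lists rose as well by camera, with adjusted p = 0.388 with an estimated correlation for the type I list and 0.328 for the others. In AB1 all 23 tested members of the type II interferon list rose (median 1.42), among them Icam1 at 1.46 ± 0.21, Gbp8 at 2.11 ± 0.38 and the T cell attracting chemokine gene Cxcl9 at 2.08 ± 0.40. All 25 of the type I list rose (median 0.72), including Oas3 at 1.33 ± 0.22, Irf7 at 1.15 ± 0.19 and Parp14 at 1.11 ± 0.20. All 18 of MHC class I presentation rose (median 1.05), including H2-Q7 at 1.34 ± 0.20, H2-D1 at 1.08 ± 0.16 and B2m at 0.96 ± 0.15. All 9 of MHC class II presentation rose (median 1.54), including H2-DMb2 at 1.54 ± 0.21, H2-DMb1 at 1.56 ± 0.22, Ctss at 1.25 ± 0.17 and H2-Ab1 at 1.63 ± 0.23. Counts adjusted over the list alone were also 23, 25, 18 and 9. Camera adjusted p were 1.27e-08, 4.5e-07, 4.55e-08 and 2.25e-05. Score permutation gave adjusted p from 4.86e-05 to 0.000537. Interferon and NK themes are known from the study's own work on these samples, so the direction of those lists is not independent evidence. Interferon scores averaged 9.32 ± 0.476 in responders and 7.40 ± 1.06 in non-responders (SD, n = 12), with responder 12 at 7.82 and non-responder 7 at 9.22.

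Several myeloid and cytokine lists rose in AB1 too by camera, with adjusted p = 0.328 with an estimated correlation for each. In the neutrophil list 11 rose and 1 fell of 12 (median 2.09), including the receptor genes Csf3r at 2.14 ± 0.23 and Cxcr2 at 2.48 ± 0.31, and Trem1 at 1.97 ± 0.24. Chemokines had 12 higher and 1 lower of 17 (median 1.36), led by the neutrophil attractants Cxcl1 at 2.78 ± 0.33, Cxcl3 at 2.75 ± 0.35 and Cxcl5 at 2.68 ± 0.33. Of 15 inflammatory cytokines 13 rose (14 adjusted over the list alone; median 1.45), including Csf3 at 2.73 ± 0.43, Il27 at 2.03 ± 0.32 and Il18 at 0.88 ± 0.13. Monocyte genes had 8 higher and 1 lower of 10 (median 1.44), including Ccr2 at 1.26 ± 0.17 and Ly6i at 2.45 ± 0.35. Macrophage genes had 8 higher and 1 lower of 15 (median 0.26), including Fcgr1 at 1.29 ± 0.19, C1qb at 0.99 ± 0.15 and C1qc at 0.99 ± 0.15. Type 1 conventional dendritic cells had 10 higher of 12 (median 0.92), including Batf3 at 1.48 ± 0.19, Irf8 at 1.51 ± 0.19 and Ppt1 at 1.1 ± 0.12. Mast cells and eosinophils had 5 higher of 6 (median 1.1), including Kit at 0.84 ± 0.13, Fcer1a at 1.74 ± 0.29 and Ms4a2 at 1.43 ± 0.29. Counts adjusted over the list alone did not differ elsewhere in this paragraph. Camera adjusted p were 4.47e-05, 0.000141, 2.75e-05, 0.000927, 0.0189, 9.02e-05 and 0.0347 in that order. Score permutation adjusted p ran from 4.86e-05 to 0.000544. With the replicate number as a block the mast cell and eosinophil list did not pass (adjusted p = 0.0564).

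Matrix and cell cycle lists fell in AB1 responders. Of 17 fibroblast and matrix genes, 13 fell and 1 rose (14 and 1 adjusted over the list alone; median -0.65), including Fap, a protease of activated fibroblasts, which fell by 1.19 ± 0.18, and Col5a2, which fell by 0.63 ± 0.09 (camera adjusted p = 0.000409, adjusted p = 0.328 with an estimated correlation, score permutation adjusted p = 6.8e-05). Of 19 proliferation genes 15 fell (17 adjusted over the list alone; median -0.37), including the mitotic kinase gene Cdk1 at -0.52 ± 0.13, Ccnb1 at -0.53 ± 0.14 and Birc5 at -0.42 ± 0.11, while Mki67 was at -0.29 ± 0.13 (adjusted p = 0.052). The camera adjusted p of that list was 0.0059, with adjusted p = 0.667 with an estimated correlation, and its score differed in the second flow cell (-0.49, exact permutation p = 0.00233, n = 7 per group) but not in the first (-0.18, exact permutation p = 0.548, n = 5 per group). Hypoxia and glycolysis passed camera at 0.0481 with 4 of 17 members higher (4 adjusted over the list alone; median 0.13), including Pfkfb3 at 1.51 ± 0.21, Pfkfb4 at 0.78 ± 0.11 and Hk2 at 0.92 ± 0.22, which regulate or begin glycolysis, and adjusted p = 0.704 with an estimated correlation. Its score difference was 0.58 in the second flow cell (exact permutation p = 0.00117, n = 7 per group) and 0.23 in the first (exact permutation p = 0.794, n = 5 per group).

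The other AB1 lists did not pass camera. Medians and adjusted p were 0.43 and 0.0592 for B and plasma cells (4 of 10 higher; adjusted p = 0.0498 with the replicate number as a block), 0.84 and 0.0655 for plasmacytoid dendritic cells (5 higher, 2 lower of 8), 0.52 and 0.107 for other dendritic cells (7 higher, 1 lower of 11). They were -0.15 and 0.519 for the TGF-beta response (2 higher, 5 lower of 13), -0.06 and 0.972 for endothelium (3 higher, 4 lower of 13), -0.10 and 0.972 for lymphatic endothelium (0 of 7) and -0.06 and 0.279 for oxidative phosphorylation (2 higher, 6 lower of 21). The immediate early list had a median of -0.01, a mean of 0.19 and an upward test (adjusted p = 0.425, 6 of 13 higher). Among lists of other tissues, values were -1.78 and 0.425 for skin (3 of 4 lower), -0.71 and 0.854 for skeletal muscle (1 of 11 lower), -0.80 and 0.763 for fat (1 higher, 1 lower of 9), -0.78 and 0.640 for blood (0 of 5), -0.64 and 0.643 for mesothelium (1 of 2 lower), -0.73 and 0.138 for renal tubule (2 of 2 lower) and -1.87 and 0.220 for the 1 tested mammary gene, which was lower. Counts adjusted over the list alone differed for the immediate early list (4), oxidative phosphorylation (2 higher, 5 lower) and skeletal muscle (0). Score permutation passed for 6 of these lists, with adjusted p = 6.8e-05 for renal tubule and for the mammary gene, 0.00034 for plasmacytoid dendritic cells, 0.000874 for the TGF-beta response, 0.0019 for B and plasma cells and 0.019 for other dendritic cells, and fry passed for the same 6. Within flow cells, 21 of 34 list scores passed an exact permutation test in the first and 24 in the second.

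**Figure D1:**
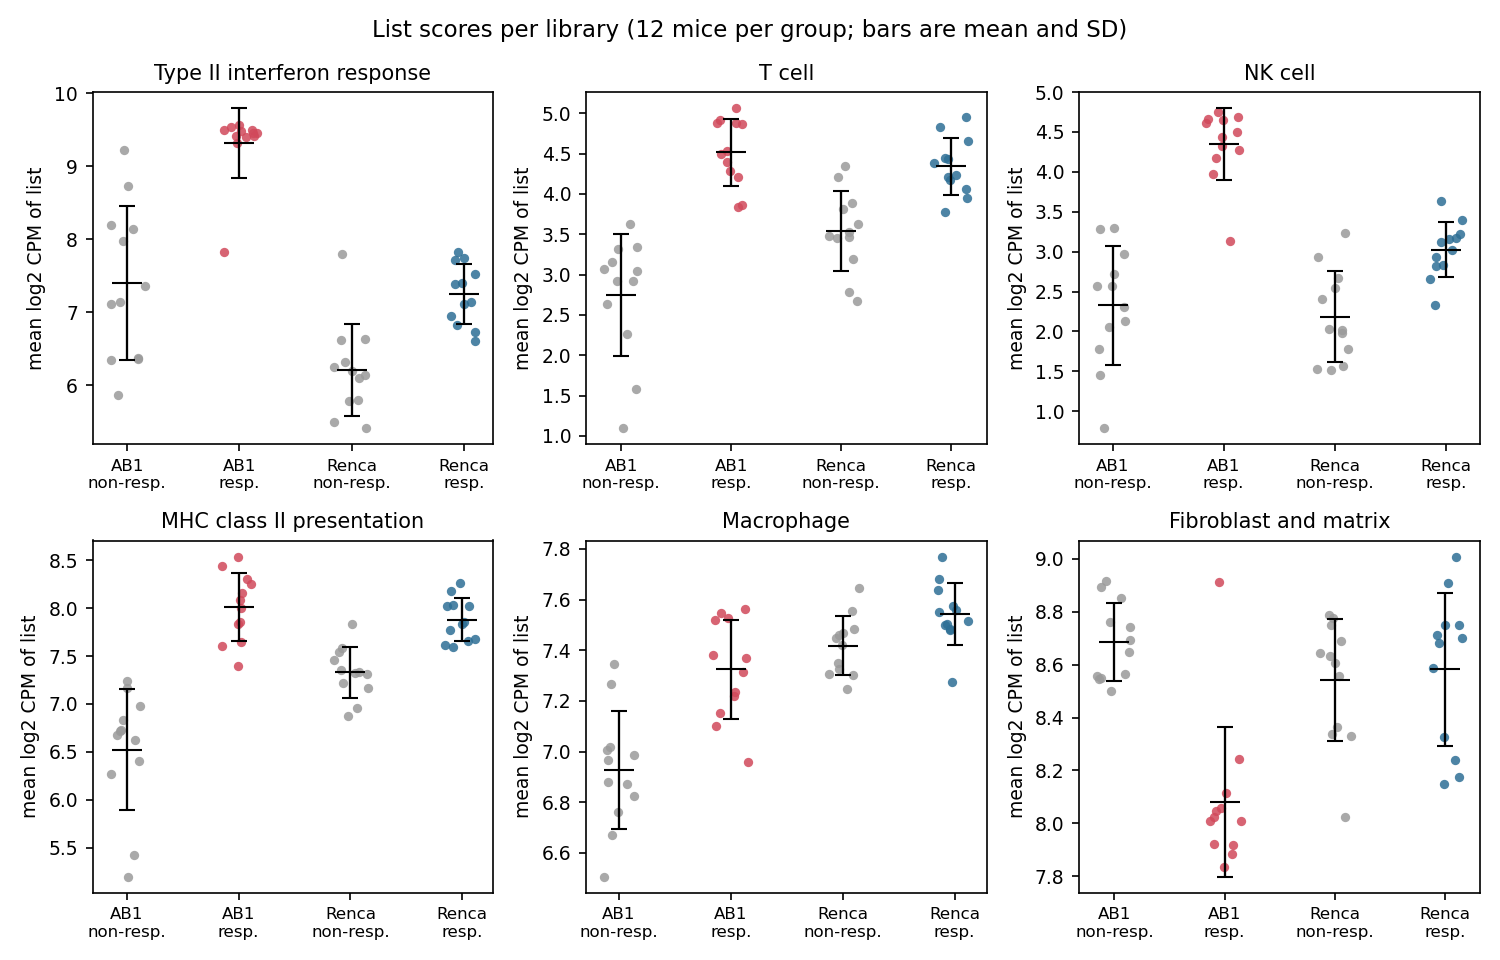
Scores of 6 gene lists (mean log2 CPM of the members, vertical axis) in each of the 48 libraries, by tumour and response; points are libraries and bars are the mean and SD of 12 mice. The type II interferon score averages 9.32 in AB1 responders and 7.40 in AB1 non-responders, and 7.25 and 6.21 in Renca. For that score responders and non-responders overlap in both tumours, while for the T cell and MHC class II scores they do not overlap in AB1.

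In Renca tumours of responders, Pdcd1 rose by 1.47 ± 0.23 (adjusted p = 0.00249), from 8.41 ± 3.45 to 23.8 ± 9.57 CPM (SD, n = 12), with 12 of 12 responders above the non-responder median. The interferon-inducible Ido1, a tryptophan-degrading enzyme, rose by 1.41 ± 0.38, Ubd by 1.36 ± 0.37, Gbp6 by 1.22 ± 0.30 and Cxcl9 (chromosome 5, 92321347 to 92328079) by 1.26 ± 0.37. Klrc2 rose by 1.35 ± 0.28, Klrc1 by 1.29 ± 0.27, Acod1 by 1.34 ± 0.45, the chemokine gene Ccl4 by 1.26 ± 0.27 and Fam26f by 1.19 ± 0.28. The call of Acod1 was lost in 16 of 24 fits that left out 1 library (highest adjusted p = 0.0711). In edgeR 3095 of 15778 genes passed, 1750 higher and 1345 lower, and 70 changed by at least 1 on the log2 scale, 67 higher and 3 lower. Within the first flow cell edgeR called 0 genes (2803 at an unadjusted p under 0.05, 192 by DESeq2) and within the second 1253 (874 higher, 379 lower). The count was 203 with RNA purity ratios as covariates (127 higher, 76 lower). It was 1040 in 1 fit of all libraries (501 higher, 539 lower), where the balance turned. With the pan-leukocyte score as a covariate it was 0 in edgeR (484 at an unadjusted p under 0.05, no other tool run), and that score correlated at 0.701 with response.

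Falls in Renca responders were smaller. Mucl1 fell by 1.06 ± 0.29, Kcne3, a potassium channel subunit, by 0.96 ± 0.19, Ccl17, a chemokine of dendritic cells, by 0.96 ± 0.25 and Plet1 by 0.92 ± 0.25. Fmo2, a monooxygenase, fell by 0.81 ± 0.13 (adjusted p = 0.00253, 0 of 12 responders above the non-responder median). Akap5 fell by 0.79 ± 0.19, Slc5a5, the iodide transporter, by 0.74 ± 0.25 (adjusted p = 0.0431), Asgr2 by 0.73 ± 0.17, Fcrls by 0.72 ± 0.15 and Mmp12, the macrophage elastase, by 0.67 ± 0.17. Of 7 tested renal tubule genes 4 fell (4 adjusted over the list alone; median -0.21), including Cdh16, a kidney cadherin, which fell by 0.38 ± 0.07, and Pax2, which fell by 0.24 ± 0.06 (camera adjusted p = 0.00197, adjusted p = 0.195 with an estimated correlation, score permutation adjusted p = 0.0035). The proliferation list was lower by camera (adjusted p = 0.000698, adjusted p = 0.498 with an estimated correlation), although 1 of 19 members passed (0 adjusted over the list alone; median -0.12). That member, Mcm2, fell by 0.18 ± 0.05, Mcm3 was at -0.13 ± 0.05 (adjusted p = 0.0524), Mcm6 at -0.13 ± 0.05 (0.0584) and Mki67 at -0.14 ± 0.07 (0.173), and the score permutation adjusted p was 0.112. Mcm2 stood at -0.15 without non-responder 4 (adjusted p = 0.0545) and at -0.15 without responder 8 (0.0514). Slc5a5 lost its call in 15 of 24 fits that left out 1 library (highest adjusted p = 0.0854) and stood at -0.71 with the replicate number as a block (adjusted p = 0.0573).

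Interferon, antigen presentation and lymphocyte lists rose in Renca by camera, with adjusted p = 0.238 with an estimated correlation for the type I list and 0.195 for the other 8 in this paragraph. All 23 type II interferon genes rose (median 0.98), among them Irgm2 at 0.80 ± 0.17, Irf1 at 0.65 ± 0.14 and Cd274 at 0.45 ± 0.11. Of 25 type I genes 18 rose (22 adjusted over the list alone; median 0.43), including Parp14 at 0.56 ± 0.12, Zbp1 at 0.64 ± 0.16 and Irf9 at 0.25 ± 0.06. MHC class I had 18 of 18 higher (median 0.43), including H2-T22 at 0.43 ± 0.09, H2-M3 at 0.32 ± 0.06 and Psmb8 at 0.50 ± 0.10. MHC class II had 9 of 9 (median 0.51), including H2-Eb1 at 0.73 ± 0.13, H2-Aa at 0.67 ± 0.12, H2-DMa at 0.51 ± 0.09 and H2-Ab1 at 0.64 ± 0.12. T cells had 19 of 21 (median 0.83), including Lck at 0.74 ± 0.14, Cd4 at 0.70 ± 0.14 and Cd6 at 0.88 ± 0.18. Cytotoxic lymphocytes had 10 of 10 (median 1.1), including Nkg7 at 1.12 ± 0.22, Cd8b1 at 1.08 ± 0.21 and Cd8a at 1.18 ± 0.24. NK cells had 13 of 15 (14 adjusted over the list alone; median 0.73), including Klrk1 at 0.91 ± 0.19 and Ncr1 at 0.57 ± 0.19. Regulatory T cells had 10 of 12 (11 adjusted over the list alone; median 0.60), including Ccr8 at 0.89 ± 0.21, Izumo1r at 0.68 ± 0.16, Ikzf2 at 0.51 ± 0.13 and Foxp3 at 0.59 ± 0.18. Checkpoint molecules had 10 of 15 (11 adjusted over the list alone; median 0.47), including Lag3 at 1.07 ± 0.17, Vsir at 0.25 ± 0.05 and Ctla4 at 0.93 ± 0.26. Where no second count is given it was the same adjusted over the list alone. Camera adjusted p ran from 2.35e-18 to 1.91e-06. Score permutation adjusted p ran from 0.00034 to 0.0105. Ncr1 lost its call in 15 of 24 fits that left out 1 library (highest adjusted p = 0.0716). The directions of the interferon and NK lists are again not independent evidence.

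Other leukocyte lists that rose in Renca had 4 of 11 B and plasma cell genes higher (4 higher, 1 lower adjusted over the list alone; median 0.33), including Ighm at 0.61 ± 0.12, Cd22 at 0.63 ± 0.14 and Ighd at 0.69 ± 0.16. Type 1 dendritic cells had 7 of 12 (9 adjusted over the list alone; median 0.33), including Cadm1 at 0.61 ± 0.12, Irf8 at 0.57 ± 0.12 and Batf3 at 0.53 ± 0.13. Plasmacytoid dendritic cells had 4 of 7 (6; median 0.52), including Spib at 0.49 ± 0.11, Pacsin1 at 0.59 ± 0.16 and Klk1 at 0.60 ± 0.17. Macrophages had 8 higher and 1 lower of 15 (the same adjusted over the list alone; median 0.13), including Csf1r at 0.21 ± 0.04, C1qa at 0.35 ± 0.07 and C1qb at 0.38 ± 0.07. Monocytes had 5 of 9 (6; median 0.49), including Ly6c2 at 0.86 ± 0.22, Ly6i at 0.99 ± 0.26 and Ms4a4c at 0.60 ± 0.18. Neutrophils had 4 of 10 (4; median 0.48), including Csf3r at 0.62 ± 0.11, Clec4d at 0.66 ± 0.19 and Clec4e at 0.80 ± 0.25. Chemokines had 8 of 16 (9; median 0.39), including Ccl8 at 0.77 ± 0.15 and Cxcl16 at 0.35 ± 0.08. Inflammatory cytokines had 5 of 14 (6; median 0.44), including Il10 at 1.04 ± 0.23, Il27 at 1.06 ± 0.24 and Il12b at 0.77 ± 0.18. Camera adjusted p ran from 4.9e-06 to 0.00304, becoming adjusted p = 0.211 with an estimated correlation for B and plasma cells and 0.195 for the others. Score permutation adjusted p ran from 0.0035 to 0.0329. Immediate early genes (2 of 13 higher, 2 over the list alone; median 0.19) and fat genes (2 of 9, 2 over the list alone; median 0.55) passed camera at 0.0376 and 0.00475, with adjusted p = 0.449 with an estimated correlation for the first and 0.377 for the second. Score permutation adjusted p was 0.0968 for both, with Atf3 at 0.64 ± 0.21, Dnajb1 at 0.19 ± 0.06, Pparg at 0.47 ± 0.16 and Lipe at 0.19 ± 0.06 passing, and Junb at 0.25 ± 0.12 (adjusted p = 0.145) and Fabp4 at 0.46 ± 0.19 (0.094) not. With the replicate number as a block the adjusted p were 0.0621 for Atf3 (0.61), 0.0707 for Dnajb1 (0.19), 0.0504 for Clec4e (0.83) and 0.0459 for Fabp4 (0.54). Calls were lost, at adjusted p of 0.05 to 0.0785, in fits that left out 1 library, 11 of 24 for Pparg, 9 for Lipe, 7 for Atf3, 4 for Dnajb1 and 1 for Clec4e (without responder 5, 0.74).

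Lists that did not pass camera in Renca had medians and adjusted p of 0.07 and 0.732 for other dendritic cells (2 higher, 1 lower of 11; mean -0.04), 0.23 and 0.0734 for mast cells and eosinophils (1 of 4 higher), 0.07 and 0.654 for fibroblasts and matrix (1 of 17 lower), 0.05 and 0.979 for the TGF-beta response (1 of 13 lower; mean -0.01). They were -0.05 and 0.267 for endothelium (1 of 13 lower), -0.44 and 0.0652 for lymphatic endothelium (2 of 6 lower), 0.03 and 0.219 for hypoxia and glycolysis (2 higher, 1 lower of 17) and 0.03 and 0.115 for oxidative phosphorylation (2 higher, 2 lower of 21). Other tissues gave -0.59 and 0.979 for skin (0 of 5), 0.78 and 0.115 for skeletal muscle (0 of 11), 0.27 and 0.979 for blood (0 of 6), 0.06 and 0.732 for mesothelium (0 of 3) and -0.15 and 0.475 for the 1 mammary gene (0 called). Counts adjusted over the list alone differed for lymphatic endothelium (3). Score permutation passed for none of these lists (smallest adjusted p = 0.0923), while fry passed for mast cells and eosinophils (adjusted p = 0.0297) and lymphatic endothelium (0.014). Within the first flow cell 0 of 34 list scores passed an exact permutation test after adjustment, and within the second 12 did. The T cell score difference was 0.75 in the first (exact permutation p = 0.0195, adjusted 0.137, n = 6 per group) and 0.85 in the second (exact permutation p = 0.00433, adjusted 0.021, n = 6 per group).

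**Figure D2:**
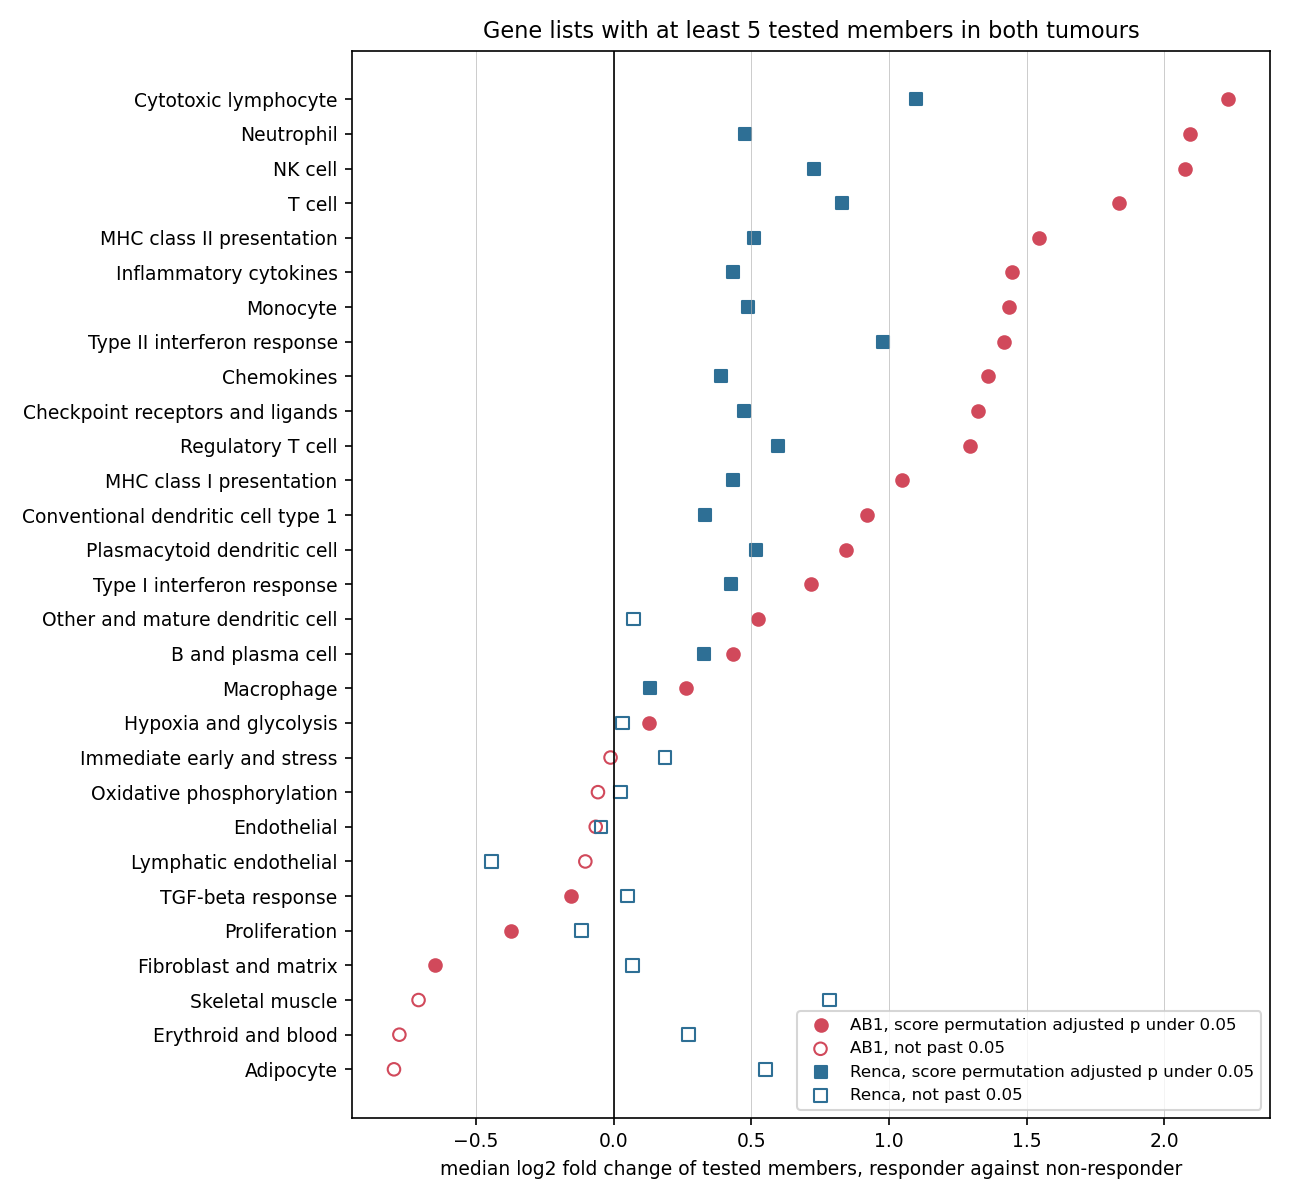
Median log2 fold change of response (horizontal axis) for gene lists with at least 5 tested members in both tumours; circles are AB1, squares are Renca, and filled symbols passed the score permutation test. The T cell list sits at 1.83 in AB1 and 0.83 in Renca, and the fibroblast and matrix list at -0.65 and 0.07.

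With both tumours in 1 model, the shared response effect was 2.28 ± 0.37 for Acod1 (adjusted p = 2.36e-06), 2.13 ± 0.32 for Mrgpra2b and 2.13 ± 0.33 for Mrgpra2a, which are paired receptor genes, and 2.11 ± 0.29 for Il1f9, an interleukin 36 gene. Dnase1l3 rose by 2.11 ± 0.29, Pdcd1lg2 by 2.08 ± 0.32, RP24-499N24.4 by 2.07 ± 0.28, Tlr12 by 2.00 ± 0.26, Ido1 by 1.94 ± 0.35 and Hcar2 by 1.92 ± 0.30. Falls included Col10a1, which fell by 2.37 ± 0.33, Agtr2, the angiotensin II type 2 receptor gene, which fell by 2.24 ± 0.38, Dmp1, which fell by 2.12 ± 0.34, and the pseudogene Tpt1-ps6, which fell by 4.23 ± 1.09. In Renca, Col10a1, Agtr2, Mrgpra2a, Mrgpra2b and Il1f9 were too low to be tested on their own (Col10a1 at 0.351 CPM in responders and 0.414 in non-responders) and Dmp1 did not pass (-0.50, adjusted p = 0.144). The difference between tumours passed for these 6 genes, so their values here rest on AB1. Tpt1-ps6 did not pass in AB1 (-0.42, adjusted p = 0.0956) and was not tested in Renca alone. Among skin genes, Krt5 stood at -3.44 ± 1.07, Dsg1a at -3.27 ± 0.99, Pkp1 at -3.02 ± 0.90, Krt14 at -2.79 ± 0.84, Dsp at -2.10 ± 0.69 and Dmkn at -1.85 ± 0.54, while in Renca alone Krt5, Krt14, Dsp and Dmkn did not pass (adjusted p = 0.479, 0.244, 0.520 and 0.167). The skin list had 5 of 7 members lower (6 adjusted over the list alone; median -2.79) and did not pass (camera adjusted p = 0.445, adjusted p = 0.833 with an estimated correlation, score permutation adjusted p = 0.13). Without AB1 non-responders 3 and 7, and with AB1 responder 3 kept, Pkp1, Krt14, Dsp and Dmkn stood at 0.051, 0.006, 0.022 and 0.01. With the replicate number as a block, Tpt1-ps6 stood at -0.94 (adjusted p = 0.207), Dsp at -0.79 (0.105) and Dmkn at -0.56 (0.193). In edgeR 9210 of 16800 genes passed, 3889 higher and 5321 lower, 605 by at least 1 on the log2 scale (488 higher, 117 lower). Within flow cells the counts were 4721 in the first and 7363 in the second.

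In the shared effect 21 of 34 lists passed camera, 19 higher and 2 lower, and 0 did with an estimated correlation (8 at an unadjusted p under 0.05, smallest adjusted p = 0.165 with an estimated correlation). Fry called 24 lists and score permutation 24. All 21 T cell genes rose (21 adjusted over the list alone; median 1.31), all 10 cytotoxic genes (10; median 1.67), all 17 NK genes (17; median 1.44) and all 23 type II interferon genes (23; median 1.22), each with adjusted p = 0.165 with an estimated correlation. Named members included Lck at 1.26 ± 0.16, Cst7 at 1.53 ± 0.18, Nkg7 at 1.72 ± 0.21, Pdcd1 at 1.80 ± 0.18 and Gbp7 at 0.99 ± 0.16. All 19 proliferation genes fell (19 adjusted over the list alone; median -0.25, adjusted p = 0.539 with an estimated correlation). Fat genes had a median of -0.19 with an upward test (adjusted p = 0.518).

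The response effects of both tumours were set against each other in 2 ways. Across 14940 genes tested in both, log2 fold changes correlated with Pearson r = 0.466 and Spearman rho = 0.394, and 64.9% had the same sign. Genes are not independent replicates, so 100 relabellings of response within each tumour, the real one included, gave the reference, and 1 of 100 was as large (p = 0.01 for r and for rho, adjusted 0.01 over the 2). Of these genes 2259 passed in both tumours, 88.3% of them in the same direction. Both were higher for 1309 genes, against 487 for independent lists, and both lower for 685, against 400. A further 112 were higher in AB1 and lower in Renca, and 153 the reverse.

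**Figure D3:**
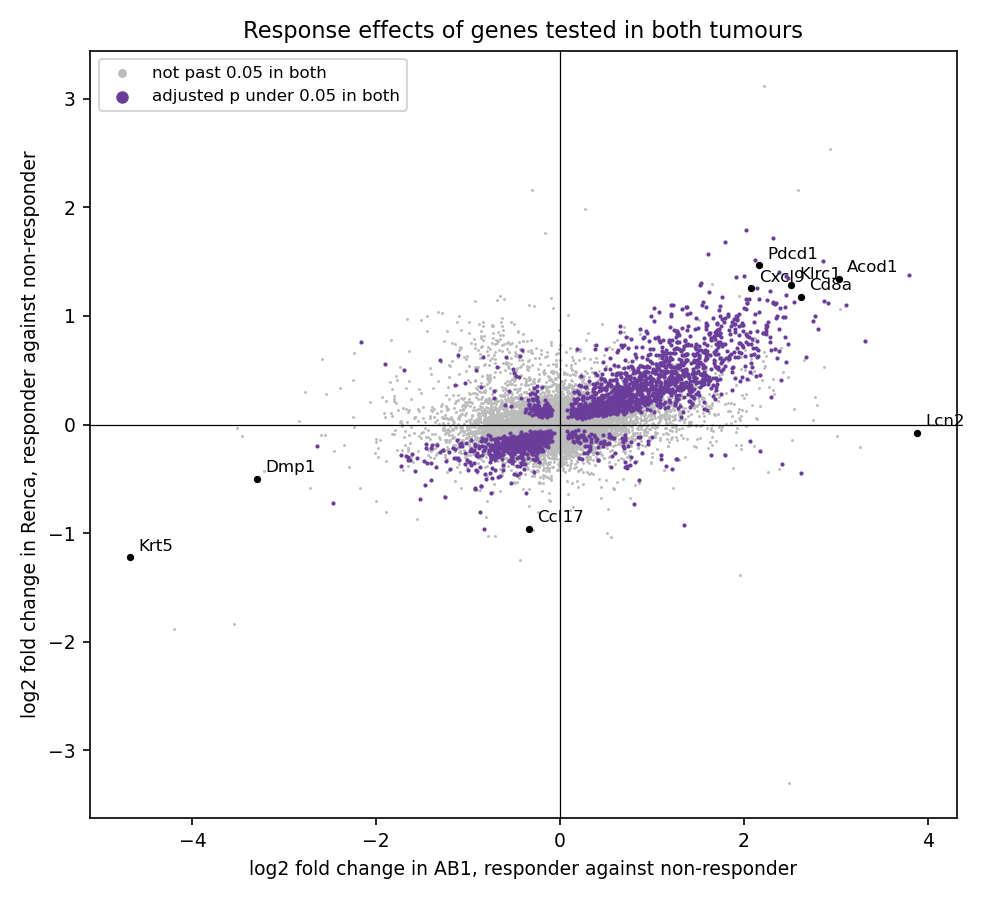
Log2 fold changes of response in AB1 (horizontal axis) and Renca (vertical axis) for 14940 genes tested in both; purple points passed in both tumours and grey points did not. Pdcd1 lies at 2.16 and 1.47, Lcn2 at 3.89 and -0.08, and Pearson r is 0.466.

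The effect of response itself differed between tumours for many genes. Card9, an adaptor of fungal recognition in myeloid cells, differed by 1.14 ± 0.11 between AB1 and Renca, Fuca2, a fucosidase, by 1.16 ± 0.11, Abr by 0.79 ± 0.08, the kinesin gene Kif3b by 0.58 ± 0.06 and Dnajc16 by 0.53 ± 0.05. In the other direction Penk, the enkephalin precursor gene, differed by -2.69 ± 0.33, Enpp1, a pyrophosphate-producing enzyme, by -1.41 ± 0.17, S100a4 by -1.17 ± 0.14, Vkorc1 by -0.72 ± 0.09 and Prdx2 by -0.50 ± 0.06. In edgeR the interaction passed for 7032 of 16920 genes, 3877 with a higher value in AB1 and 3155 with a lower one, and 1318 differed by at least 1 on the log2 scale. Within flow cells the counts were 5167 in the first and 3286 in the second. The share of these genes that was higher in AB1 was 55.1%, and 43.1% and 69.1% within the flow cells, 40.7% without the flow cell term and 41.1% without a filter.

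Cytotoxic, NK cell, T cell and neutrophil lists had larger response effects in AB1 by camera. The difference passed for 10 of 10 cytotoxic genes (10 adjusted over the list alone; median 1.28), 15 of 17 NK cell genes (16; median 1.39), 17 of 21 T cell genes (19; median 1.0) and 8 higher with 1 lower of 12 neutrophil genes (9 and 1; median 1.61). Of 11 B and plasma cell genes 2 passed (1 adjusted over the list alone; median 0.12), and that list did not (camera adjusted p = 0.63, adjusted p = 0.837 with an estimated correlation). For type II interferon genes it passed for 5 of 23 (3 adjusted over the list alone; median 0.64), although all of them rose in each tumour. Fibroblast and matrix genes had 10 lower and 1 higher of 17 (10 and 1; median -0.68), with a fall in AB1 and no passing list test in Renca. In camera 16 of 34 lists passed, 14 higher and 2 lower in AB1, with adjusted p = 0.700 to 0.755 with an estimated correlation for those 16, while fry called 16. Lists were not counted under redrawn labels for this difference. In the AB1, Renca and shared comparisons redrawn labels passed a median of 13, 11 and 11 lists by camera. The number of 16 lists is therefore not evidence of a difference by itself.

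AB1 and Renca tumours differed in most genes tested. Hoxd13, a limb patterning gene, was higher in AB1 by 10.98 ± 0.16 on the log2 scale, Col10a1 by 9.20 ± 0.39, Ptprq by 8.77 ± 0.22, Sox2 by 8.42 ± 0.26 and Nyap2 by 7.74 ± 0.42. Wfdc2 was at -13.82 ± 0.13, Cdh16 at -12.95 ± 0.14, Sall1, a kidney development gene, at -12.59 ± 0.10, Nxf3 at -12.22 ± 0.11, the pseudogene Krt8-ps at -11.76 ± 0.18 and Sult1c2 at -11.64 ± 0.12. Of 7 tested renal tubule genes 5 were lower in AB1 and 2 higher (median -10.35, camera adjusted p = 0.00254, adjusted p = 0.0981 with an estimated correlation). Of 3 tested mesothelial genes 2 were higher and 1 lower (2 and 1 adjusted over the list alone; median 0.68), and that list did not pass (camera adjusted p = 0.942, adjusted p = 0.99 with an estimated correlation). In edgeR 13241 of 16258 genes passed, 6853 higher and 6388 lower in AB1, and 3661 differed by at least 1 on the log2 scale, 1709 higher and 1952 lower. Higher lists in AB1 were type I interferon (25 of 25, median 1.36), type II interferon (23 of 23, median 1.78), NK cells (16 of 17, 17 adjusted over the list alone, median 1.28). So were monocytes (10 of 10, median 2.31), neutrophils (11 of 11, median 1.91), mast cells and eosinophils (6 of 6, median 3.24) and chemokines (13 of 17, 1 lower, median 1.53). Except for NK cells the counts were the same adjusted over the list alone. Their camera adjusted p ran from 1.19e-06 to 0.0222, and from adjusted p = 0.877 to 0.99 with an estimated correlation. The tumours were sequenced on different flow cells and removed on different days, so these cannot be separated from the line.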

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

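The T cell, abundant-gene, pan-leukocyte, skeletal muscle and skin tests, and the fits without AB1 non-responders 3 and 7 or responder 3, were chosen after the results were seen.

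The response effect differed between AB1 and Renca, by the interaction test of edgeR, for 120 of 189 genes named in the text, 96 higher and 24 lower in AB1, and 69 did not pass it. Apart from a fixed panel, those genes were picked by their values in these same data, some by the interaction p itself. Their share and direction are therefore partly built in. Over all genes 7032 of 16920 passed (41.6%), 3877 higher and 3155 lower in AB1, and that balance turned between settings. Values are the AB1 effect minus the Renca effect on the log2 scale. Among inflammatory and neutrophil genes the differences were 4.0 for Lcn2, 2.57 for Cxcl1, 2.09 for Cxcl5, 2.08 for Cxcr2, 1.56 for Csf3r, 2.35 for Il1f9, 1.96 for Hcar2, 2.56 for Mrgpra2b, 2.64 for Mrgpra2a, 1.73 for Acod1, 1.0 for Il27 and 1.14 for Card9. Lymphocyte genes differed by 1.49 for Cd8a, 1.40 for Eomes, 1.32 for Cst7, 1.24 for Nkg7, 1.24 for Cd247, 1.09 for Lck, 1.54 for Ncr1, 1.27 for Klrc1, 1.16 for Klrc2 and 0.92 for Cd22. Interferon, presentation and checkpoint genes differed by 1.73 for Cd274, 2.60 for Pdcd1lg2, 0.90 for Icam1, 0.77 for Irf1, 1.31 for Fam26f, 0.84 for H2-D1, 0.67 for B2m, 1.03 for H2-Ab1 and 0.90 for H2-Eb1. Pdcd1 (0.73, adjusted p = 0.0665) and Cxcl9 (0.86, 0.2) did not pass that test. Macrophage and other genes differed by 0.64 for C1qb, 0.91 for Fcgr1, 2.04 for Dnase1l3, 1.77 for Tlr12, 3.16 for Inpp5j, 1.84 for RP24-499N24.4, 1.47 for Pfkfb3, 1.16 for Fuca2, 0.79 for Abr, 0.58 for Kif3b and 0.53 for Dnajc16. Akap5 differed by 0.93, with a fall in Renca (-0.79) and no passing change in AB1 (0.11, adjusted p = 0.578). Other lymphocyte, checkpoint and mast cell genes differed by 1.40 for Cd8b1, 1.11 for Klrk1, 1.35 for Sh2d1a, 1.29 for Txk, 0.44 for Il18rap, 2.14 for Gpr83, 1.18 for Izumo1r, 0.66 for Tnfrsf18, 0.58 for Ikzf2, 1.0 for Cd86, 0.49 for Vsir, 1.89 for Fcer1a and 1.70 for Ms4a2. Other interferon and presentation genes differed by 1.1 for Oas3, 1.20 for Gbp8, 0.59 for Parp14, 0.73 for Zbp1, 0.67 for Psmb8, 0.91 for H2-Q7, 0.59 for H2-T22, 0.56 for H2-M3, 0.93 for H2-Aa, 0.98 for H2-DMa, 1.07 for H2-DMb1, 1.13 for H2-DMb2 and 0.80 for Ctss. Other myeloid, chemokine and cytokine genes differed by 2.75 for Cxcl3, 0.99 for Cxcl16, 0.71 for Il18, 2.19 for Trem1, 0.97 for Clec4d, 1.68 for Clec4e, 1.1 for Ccr2, 1.25 for Ly6c2, 1.49 for Ly6i, 0.83 for Ms4a4c, 0.59 for C1qa, 0.66 for C1qc, 0.36 for Csf1r, 0.99 for Batf3, 0.98 for Irf8, 1.05 for Ppt1 and 0.81 for Pacsin1. Glycolysis, fat, bone and other genes differed by 0.69 for Pfkfb4, 0.78 for Hk2, 0.40 for Lipe, 1.49 for Alpl, 0.62 for Car2 and 1.31 for Clcn7, and by -1.94 for Acp5, -2.64 for Atp6v0d2, -1.73 for Ctsk, -1.52 for Ocstamp, -2.51 for Phex, -1.22 for Fabp4, -0.30 for Dnajb1 and -1.89 for Krt8-ps. Il1f9, Mrgpra2a, Mrgpra2b, Fcer1a, Ms4a2 and Phex were too low to be tested in Renca alone, and Krt8-ps in AB1 alone. Their differences therefore rest in part on very low counts.

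Lower effects in AB1 were found for matrix genes, at -1.06 for Col3a1, -0.68 for Col5a2, -1.11 for Fap, -2.53 for Col10a1 and -2.77 for Dmp1, and for Agtr2 (-2.62), Penk (-2.69), Enpp1 (-1.41), S100a4 (-1.17), Vkorc1 (-0.72), Prdx2 (-0.50) and Fcrls (-1.72). Col10a1 and Agtr2 were too low to be tested in Renca alone. Among genes that rested on a few libraries, Trim29 was at -3.42, Cdsn at -3.36, S100a3 at -3.03, Amd2 at -2.88, Tpt1-ps5 at 3.77 and Tpt1-ps6 at 7.0. Plet1 and Asgr2 rose in AB1 and fell in Renca, with differences of 2.31 and 1.57. Of 34 lists 16 differed by camera, and their median differences were 1.61 for neutrophils, 1.39 for NK cells, 1.28 for cytotoxic lymphocytes, 1.0 for T cells, 0.98 for MHC class II, 0.96 for chemokines, 0.96 for monocytes, 0.84 for inflammatory cytokines, 0.68 for regulatory T cells, 0.64 for MHC class I, 0.64 for the type II interferon response, 0.59 for checkpoint molecules, 0.51 for type 1 dendritic cells, 0.47 for the type I interferon response, -0.25 for proliferation and -0.68 for fibroblasts and matrix. With an estimated correlation those 16 lists had adjusted p = 0.700 to 0.755, while fry called 16. The number of lists was not set against redrawn labels for this difference, so chance is not excluded for it.

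T cell and cytotoxic genes rose in responders of both tumours. A lower share of tumour cells would raise all other cell types alike, yet the T cell score rose above the endothelial score by 1.83 ± 0.28 in AB1 (permutation p = 1e-05, the smallest it can give) and 0.85 ± 0.21 in Renca (permutation p = 0.00061), which argues against it as the whole cause. A larger leukocyte share raising each leukocyte type alike meets the same objection, since the T cell score rose above the macrophage score by 1.37 ± 0.21 (permutation p = 1e-05) and 0.68 ± 0.15 (permutation p = 0.00017). A lower tumour cell share as a part of the cause stays open. Of 44 genes over 32-fold higher in AB1 tumours than in Renca, 28 fell and 7 rose in AB1 responders. In Renca responders 4 of 7 renal tubule genes fell and 0 rose. The share of counts left outside the 10 most abundant genes differed by 0.029 ± 0.0034 on the log2 scale in AB1 and by -0.0035 ± 0.0037 in Renca, against T cell medians of 1.83 and 0.83, which argues against a few genes taking the counts. More leukocytes of the kinds that rose cannot be told apart from a change within them: with the pan-leukocyte score as a covariate the T cell medians were -0.23 and 0.079, but that score itself tracked response.

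Several skin genes fell in AB1 responders, while the skin list, with 3 of 4 tested members lower, did not pass (camera adjusted p = 0.425, score permutation adjusted p = 0.132). Of 36 other epidermal genes 27 had counts in AB1 non-responders. All 27 had non-responder 3 in their highest pair, and 16 had non-responders 3 and 7, where chance gives 1.52%, or 9.09% with non-responder 3 as given. Skin genes vary together, and the 2 libraries were picked by skin genes of the same data, so these shares are no test of chance. Non-responder 7 had 0 CPM of Krt71 and Krt27. Skin taken with those 2 tumours is a likely source, more clearly for non-responder 3. Whether the other libraries also differed cannot be told apart from it: the median of the 6 named skin genes, -3.34 with all libraries, was 0.39 (median SE 0.788) without those 2, and -1.09 (median SE 0.465) when responder 3, with 21.6 CPM of Krt5, was left out too. Responder 3 shared a lane with non-responder 3. Krt5 stood at 21.6 CPM in responder 3 against 223 in non-responder 3, and Krt14 at 11.7 against 122. Whether the skin reads of responder 3 came from its own tumour was not tested. Non-responder 3 also had 2544 CPM of the hair follicle keratin gene Krt71 and an RNA purity ratio for salts and solvents of 1.08.

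Calls in Renca varied with the model, and with purity ratios 203 genes passed, 196 of them among the 3095, whose median signed change was 0.19, from 0.23, while the median SE grew from 0.0623 to 0.0692, so most calls ended with smaller changes and larger errors. For the T cell score, RNA purity as the whole cause is argued against, since its difference was 0.67 ± 0.19 with the ratios, from 0.80 ± 0.17. That score covers T cell genes alone, and the median signed change is over genes picked and signed by the fit without the ratios. Neither decides the question for the other calls. An effect in the second flow cell alone is argued against because genes called there differed in the same direction in the first, by a mean of 0.32 (exact permutation p = 0.0325, n = 6 per group). With the skeletal muscle score as a covariate 2606 genes passed, which argues against adjacent muscle. The index sequences cannot be told apart from response.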

How the results depend on the processing

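Muscle and pan-leukocyte covariates and the omission of AB1 non-responders 3 and 7, alone or with responder 3, were chosen after seeing the data. Counts of genes past the threshold stayed within 1.5 times of 9577 in AB1, 3095 in Renca, 9210 for the shared effect, 7032 for the difference between tumours and 13241 between tumours, except as follows. The first flow cell alone gave 5816 in AB1, 0 in Renca by edgeR (2803 at an unadjusted p under 0.05, 192 by DESeq2) and 4721 for the shared effect, and the second gave 1253 in Renca and 3286 for the difference, with fewer libraries in each. Renca had 203 with RNA purity ratios and 1040 in 1 fit of all libraries, and the cause was not tested for the latter. With the pan-leukocyte score edgeR called 0 genes in AB1 and 0 in Renca (343 and 484 at an unadjusted p under 0.05, no other tool run). Lists past camera with an estimated correlation numbered 0 in AB1, Renca and the shared effect (0, 7 and 8 at an unadjusted p under 0.05, with fry calling 24, 20 and 24), since estimated correlations were larger than the preset one. Leaving out each library gave 9069 to 9998 in AB1 and 2304 to 3954 in Renca. With the replicate number as a block, for pairs sharing a lane, the counts were 9714, 2721, 9247, 7112 and 14238, the correlation between tumours was 0.43 and lists past camera were 19, 21 and 21. The block moved no count by over 1.5 times, shared 8868, 2494, 8642, 6602 and 12796 gene calls with the fits without it, and among named genes and lists changed no call beyond those given beside their results. Directions turned for few named genes outside the pan-leukocyte fit, and the cause was not tested unless named. Purity ratios gave Dsp 0.21, Perp 0.52 and Psors1c2 0.088 in AB1, the first flow cell Tpt1-ps5 -0.65 and Amd2 0.13, and voom Dsp 0.039 and Perp 1.11. Leaving out each library, Psors1c2 ran from -4.01 to 0.32, the latter without AB1 non-responder 3. Without non-responders 3 and 7, which held skin genes, Krt5 stood at 0.32, Trim29 0.44, Cdsn 0.27, Dsp 0.60, Perp 1.17 and Psors1c2 0.35 in AB1, of which Perp alone stayed above 0, at 0.17, without responder 3 as well, and Pkp1 0.051, Krt14 0.006, Dsp 0.022 and Dmkn 0.01 for the shared effect. With the pan-leukocyte score, which correlated at 0.889 with response, AB1 values were -0.30 for Dnase1l3, -0.54 Acod1, -0.39 Tlr12, -0.28 Icam1, -0.39 Cd274, -0.44 Gbp8, -0.03 Oas3, -0.14 Irf7, -0.17 Parp14, -0.40 H2-Q7, -0.21 H2-D1, -0.17 B2m, -0.30 H2-DMb2, -0.09 Ctss, -0.29 H2-DMb1, -0.04 Cd247, -0.25 Sh2d1a, -0.068 Eomes, -0.34 Klrc1, -0.089 Txk, -0.18 Gpr83, -0.14 Izumo1r, -0.27 Tnfrsf18, -0.18 Irf8, -0.14 Batf3, -0.18 Fcgr1, -0.14 C1qc, -0.066 C1qb, -0.17 Ccr2, -0.22 Ly6i, -0.004 Pfkfb3, -0.093 Hk2, -0.35 Il27, -0.35 Ctla4, -0.56 Cxcl9, -0.29 Foxp3, -0.38 Ncr1 and -0.21 H2-Ab1, and 0.007 for Col5a2 and 0.09 for Ccnb1. In Renca, at a correlation of 0.701, they were -0.09 for Acod1, -0.004 Batf3, -0.033 Klk1, -0.033 Ly6c2, -0.012 Ly6i, -0.15 Ms4a4c, -0.24 Clec4e, -0.007 Il10, -0.13 Ctla4, -0.11 Foxp3 and 0.011 Mcm2. Small changes can be missed at this depth and spread, whose parts were not tested separately: 17 of 50 simulated genes changed by 0.25 were recovered in the AB1 comparison and 37 in Renca. Genes were simulated independently, and 200 were changed beside the T cell list, against 9577 and 3095 calls in the data. These rates therefore need not hold in the data.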

Other observations

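The bone and osteoclast tests were chosen after the falls of Dmp1, Col10a1, Col11a1 and Atp6v0d2 were seen, and genes in the next paragraph were chosen after their values were seen.

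Several bone and osteoclast genes fell in AB1 responders. Besides Dmp1 and Col10a1, AB1 falls included Phex, a regulator of bone mineral, at -2.27, Col11a1, a cartilage collagen, at -1.89, and Spp1, which encodes osteopontin, at -0.92. Among osteoclast genes falls were found for Calcr, the calcitonin receptor gene, at -3.02, Atp6v0d2 at -2.25, Acp5, the tartrate-resistant acid phosphatase gene, at -1.90, the bone collagenase gene Ctsk at -1.74 and Ocstamp at -1.64, while Clcn7 rose by 1.26 and Tcirg1 by 0.31. Alpl (0.77, adjusted p = 0.0641), Car2 (0.43, 0.0915), Runx2 (0.047, 0.492), Ifitm5 (0.009, 0.969) and Itgb3 (-0.11, 0.262) did not pass. A hypothesis is that wider sets of both kinds fell together. The score of the other bone and growth plate genes differed by -0.49 (permutation p = 2e-05, adjusted 6e-05, 3 of 6 genes fell). That of the other osteoclast genes differed by -0.73 (permutation p = 0.00285, adjusted 0.00428, 6 fell and 2 rose of 10). Both scores were lower, as the hypothesis predicts, but this is weak evidence. Among all AB1 genes 5181 of 15859 fell, and score permutation passed for 25 of the 34 fixed lists. Camera did not pass for either list (p = 0.22 and 0.223). In Renca the scores differed by -0.18 (permutation p = 0.148) and -0.0092 (permutation p = 0.86), and the difference of these scores between tumours was not tested. Of 44 genes over 32-fold higher in AB1 tumours than in Renca, 28 fell and 7 rose in AB1 responders (median -0.69), so a lower share of AB1 cells stays open for these falls.

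Labels of the same libraries were redrawn 100 times for each test, the real labels included. The real labels gave the largest value, 1 of 100 as large, for the AB1 count (9577 against a highest other of 3475) and the Renca count (3095 against 1). The same held for the shared effect (9210 against 2714) and the comparison of tumours (13241 against 4236). It also held for the correlation between tumours (Pearson r 0.466 against 0.379 and Spearman rho 0.394 against 0.382, a narrow margin). Since 1 of 100 is the smallest share this can give, chance is unlikely for these results but not excluded. For the difference between tumours 2 of 100 were as large, 7032 against 7490 in a split that kept the label of 22 of 24 AB1 libraries and 6 of 24 Renca libraries, so that it set the AB1 effect against a mostly exchanged Renca effect. Further splits gave 4893 (2 AB1 and 10 Renca libraries labelled as real) and 2117 (8 and 16). Redrawing response also removes the effect within each tumour, so the 2 of 100 cannot decide whether the effects differ. The highest AB1 split kept 20 of 24 labels, and like the real labels it parted every same-numbered pair. For the number of lists past camera chance cannot be excluded, with 26 of 100 as large in AB1 (19 against 23), 9 in Renca (21 against 24) and 12 for the shared effect (21 against 23). Medians over the other labels were 13, 11 and 11 lists.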
